A study of Mus musculus with 2 samples.

How the data were processed

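The series holds H3K27me3 ChIP-seq of kidney from newborn mice (postnatal day 0, mixed strain B6NTac;B6NCrl, males and females pooled) in 2 libraries, the biological replicates of 1 group, per the labels. The labels give a fragment size range of 300 to 500 bp for both libraries, and 15 mice for replicate 1. Each replicate is a pool of animals, so the spread between replicates is a spread between pools.

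The 4 deposited files used here are peak lists in narrowPeak format on the mm10 build, per the file headers of their descriptions. One list was made from each replicate, 1 from the alignments of both replicates pooled, and 1 of replicated peaks from the other 3 lists. All were made against a control alignment, per the labels and file descriptions. The aligner, the peak caller, their versions and the rule for calling a peak replicated are not given in the sources used here. The control was not analysed here. Each peak carries a fold enrichment (a ratio of ChIP over control, made by the authors), and a −log10 p and a −log10 q, both as deposited. All −log10 p values were above 2, as with a p threshold of 0.01, and −log10 q reached down to 0.0245, so no q threshold had been set. The deposited display score of each peak was not printed or tested. All 12000 replicated peaks are identical to pooled peaks, 10015 of them overlapped both replicates' peaks by 50% of either peak, and 1985 did not. Whether the exact number of 12000 is an upper limit set on the list is not known, and if it is, the counts and shares of replicated peaks and marked genes depend on it. A narrow peak caller splits the broad regions this mark forms, so a count of peaks depends on how they were split. The read depth is unknown, so no interval here covers counting of reads. Intervals on shares of peaks or genes are exact binomial (Clopper-Pearson, 95%) and cover the number of peaks or genes only.

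Gene models were GENCODE M21 on GRCm38, the build that mm10 names, with the GRCm38.p6 sequence. All peaks lay within the ends of the 20 chromosomes that had any, and no peak was on Y, so genes of Y and of the mitochondrion were left out of the background. Coordinates are 1-based. A promoter was the 1 kb on either side of any annotated TSS of a protein-coding gene. A gene's promoter fold was that of the strongest peak overlapping any of its promoter windows, taken separately in each list. It can thus belong to a TSS other than the 5′-most. Promoter CpG was counted in the 1 kb on either side of the 5′-most annotated TSS alone. The 21728 protein-coding genes were the background of every list.

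Peak sets were compared by overlap, with at least 50% of a peak's length covered, against 1000 placements of the second list at random on the same chromosomes, with the same widths and outside sequence gaps. Promoter shares were set against random placements in the same way. Marked and unmarked genes of 19 lists were compared with all other genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 19 lists and a threshold of 0.05. Neighbouring genes can share a peak and are not independent, which these tests do not take into account. Domains were replicated peaks merged across up to 3 kb and at least 10 kb long. The gene lists, the tests of the comparisons and the rule for named genes were fixed before the data were examined, and so were the alternatives apart from 3 added later. The scan of gene families and several tests of explanations in the closing section were chosen after the result was seen, as stated there. That rule takes the 20 marked genes with the highest promoter fold, the 10 longest domains, up to 6 marked members of each list by fold and up to 6 unmarked in list order, every Hox gene, and the 5 peaks of each replicate with the highest −log10 p that no peak of the other overlaps. The grouping of Hox genes by paralogue, and all names and families outside that rule in the closing section, were chosen after their values were seen.

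The alternatives were an overlap of 1 bp or 50% of both peaks, peaks of q 0.01 or less, equal numbers of top peaks, promoter windows of 500 bp and 2.5 kb, the pooled list, each replicate's list by itself (leaving out the other), a single TSS per gene, a background matched on promoter CpG in 10 bins (100000 random sets), merging gaps of 1 and 10 kb, and −log10 p as strength. Added later were the overlap without chromosome X, TSSs of protein_coding transcripts alone, and replicated peaks that overlap both replicates' own lists by 50% of either peak. In 21728 genes, all of 200 genes given a simulated peak at their TSS were recovered as marked, which the window makes certain. On the real marks, 4.00% of 200 lists of genes drawn at random were called at an unadjusted p of 0.05. Such lists are scattered, so this does not cover lists of neighbouring genes that share peaks. With 39.9% of 12000 peaks kept in place and the rest placed at random, the overlap found was 39.9%. The steps ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and the overlap function was checked against bedtools 2.31.1.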

Results

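H3K27me3, the trimethylation of lysine 27 of histone H3 that Polycomb repressive complexes place on silent genes, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole kidney of mice on the day of birth (postnatal day 0). The series has 1 group with 2 biological replicates, each made from kidneys pooled over newborn males and females, 15 mice for replicate 1 and an unstated number for replicate 2. Replicate 1 was sequenced as 2 technical replicates and replicate 2 as 1. There is no second condition, so the comparisons are between the replicates, between the places in the genome that carry a peak, and between groups of genes. The deposited lists held 42200 peaks for replicate 1, 27748 for replicate 2, 41320 for both replicates pooled and 12000 called replicated, which covered 15.1, 11.2, 18.4 and 10.7 Mb of the mm10 genome. The number of reads behind each list is unknown here, so the lists' lengths could not be set against depth. Fold enrichment over the control and −log10 p of each peak are the authors' values. In the main results they were used only to rank and describe peaks. Some tests in the closing section also compare folds.

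The genes with the strongest replicated promoter peaks included many of the nervous system and of organs other than kidney. The highest fold was at Lhx3, a LIM-homeodomain gene of motor neurons and pituitary, on chromosome 2 from 26200757 to 26205594 (fold 8.94). The strongest Lhx3 promoter peaks in the replicates' own lists had folds of 7.41 in replicate 1 and 8.59 in replicate 2. Six3, a forebrain and eye regulator, followed with a fold of 8.77 (chromosome 17, 85610477 to 85619454), and then Insm1, a neuroendocrine zinc finger gene, with 8.43. Nkx3-2, which acts in the axial skeleton, had 8.26, and the potassium channel gene Kcnk9 and the spinal cord gene Olig3 both had 8.09. The other genes among the 20 with the highest promoter fold were Crmp1, Nefh, Prdm13, Bhlhe23, Rbfox3 (the neuronal marker NeuN), Dio3, Hand1, Onecut3, Slc32a1 (the vesicular GABA transporter), Tbx4, Neurod2, Olig2, Vax2 and Adra2c, whose folds lay between 7.92 and 7.37. All 20 had a promoter peak in each replicate's own list, with folds from 4.71 to 8.21 in replicate 1 and from 4.74 to 8.59 in replicate 2. Of the 20, 11 belong to a neural, neuronal, muscle, endoderm or limb list fixed before the data were examined.

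A gene was called marked when a replicated peak overlapped the 1 kb on either side of any of its transcription start sites (TSSs). Of 21728 protein-coding genes on the autosomes and X, 2198 (10.1%) were marked. It is not known here whether the list of exactly 12000 replicated peaks was limited in number. If it was, this share depends on the limit. A promoter peak was present in both replicates' own lists for 2056 of these 2198, and in neither for 4. Replicate 1's list alone marked 3355 genes and replicate 2's 2867, and 2354 genes were marked in both, against 443 if the lists were independent. The count thus rose more than 1.5 times when replicate 1's list was used by itself, and to 3581 with the pooled list. Marked genes had CpG-rich promoters more often: 0.414% of genes were marked in the lowest of 10 equal bins of promoter CpG and 17.4% in the highest. Of the marked genes named here, Bmi1, Cbx7, Cdkn2c, Hoxc6, Hoxd3, Olfr71, Olfr94, Runx1, Runx3, Zfp316 and Zfp64 were not marked with a single TSS per gene, Cbx4 and Hoxc6 had no promoter peak in replicate 2's list, and Olfr71 had none in replicate 1's. With a 500 bp window Cbx4, Cbx8, Ddx25, Hoxa1, Hoxb1, Hoxc6, Hoxc11 and Hoxd12 were not marked, and with peaks of q 0.01 or less Hoxb1 and Hoxc6 were not. Of the unmarked genes named here, Pax2, Mesp2, Bcl11b and Hoxd11 had a promoter peak in both replicates' own lists. Promoter peaks of Cited1, Slc34a1, Cubn, Prrx1, Sp7, Tcf7, Pecam1, Plvap, Gria1, Ezh1, Rbbp7, Cdkn1a and Hoxd4 were in replicate 1's list and not in replicate 2's, and those of Tcf21, Myf6 and Hoxa3 were in replicate 2's and not in replicate 1's. Wnt8a, Cdkn1c, Ezh2 and Hoxb9 had one in the pooled list only.

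Most transcription factors of lineages outside the kidney were marked. In the neural list 46 of 48 genes were marked (95.8%, exact 95% interval 85.7 to 99.5%), against 9.93% of other genes (Fisher's exact test, two-sided, adjusted p = 9.69e-43). Its strongest members were Lhx3, Olig3, Olig2, Neurod2, Phox2b (fold 7.33) and Pou4f1 (7.33), and the members without a replicated promoter peak were Neurod4 and Neurod6. All 21 endoderm factors were marked (exact adjusted p = 7.40e-21), led by Insm1, Onecut3, the pancreatic genes Ptf1a (6.87) and Pdx1 (6.44), Pax9 (6.57) and the intestinal gene Cdx2 (6.24). Of 21 limb and skeletal factors, 19 were marked (exact adjusted p = 6.32e-17), led by Nkx3-2, Tbx4, Msx1 (6.41), Satb2 (5.86), Pax1 (5.73) and Pitx1 (5.39), and Prrx1 and Sp7 were not. Of 20 cardiac and skeletal muscle factors, 16 were marked (exact adjusted p = 8.86e-13), led by Hand1, Irx4 (7.25), Tbx20 (6.91), Pitx2 (6.79), Tbx5 (6.74) and Nkx2-5 (6.74). The muscle factors Myf6, Myog, Mesp2 and Smyd1 were not marked.

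Most Wnt ligand genes and neuronal effector genes were also marked. Of 19 Wnt ligand genes, 18 were marked (94.7% against 10.04% of other genes, exact adjusted p = 6.32e-17), with Wnt3a (fold 7.25), Wnt7a (6.70), Wnt6 (6.07), Wnt9b (5.90), Wnt10b (5.86) and Wnt7b (5.73) the strongest, and Wnt8a was the exception. Of these, Wnt9b and Wnt7b are genes of the ureteric bud and collecting duct of the kidney. Among 25 neuronal effector genes, which encode synaptic proteins, transmitter transporters, channels and neurofilaments, 22 were marked (exact adjusted p = 9.47e-19). Their strongest peaks were at Rbfox3, Slc32a1, Kcnc1 (6.91), Chat (6.37), Nefl (6.07) and Gad2 (5.86), while Syn1, Gria1 and Dcx were not marked.

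**Figure D1:**
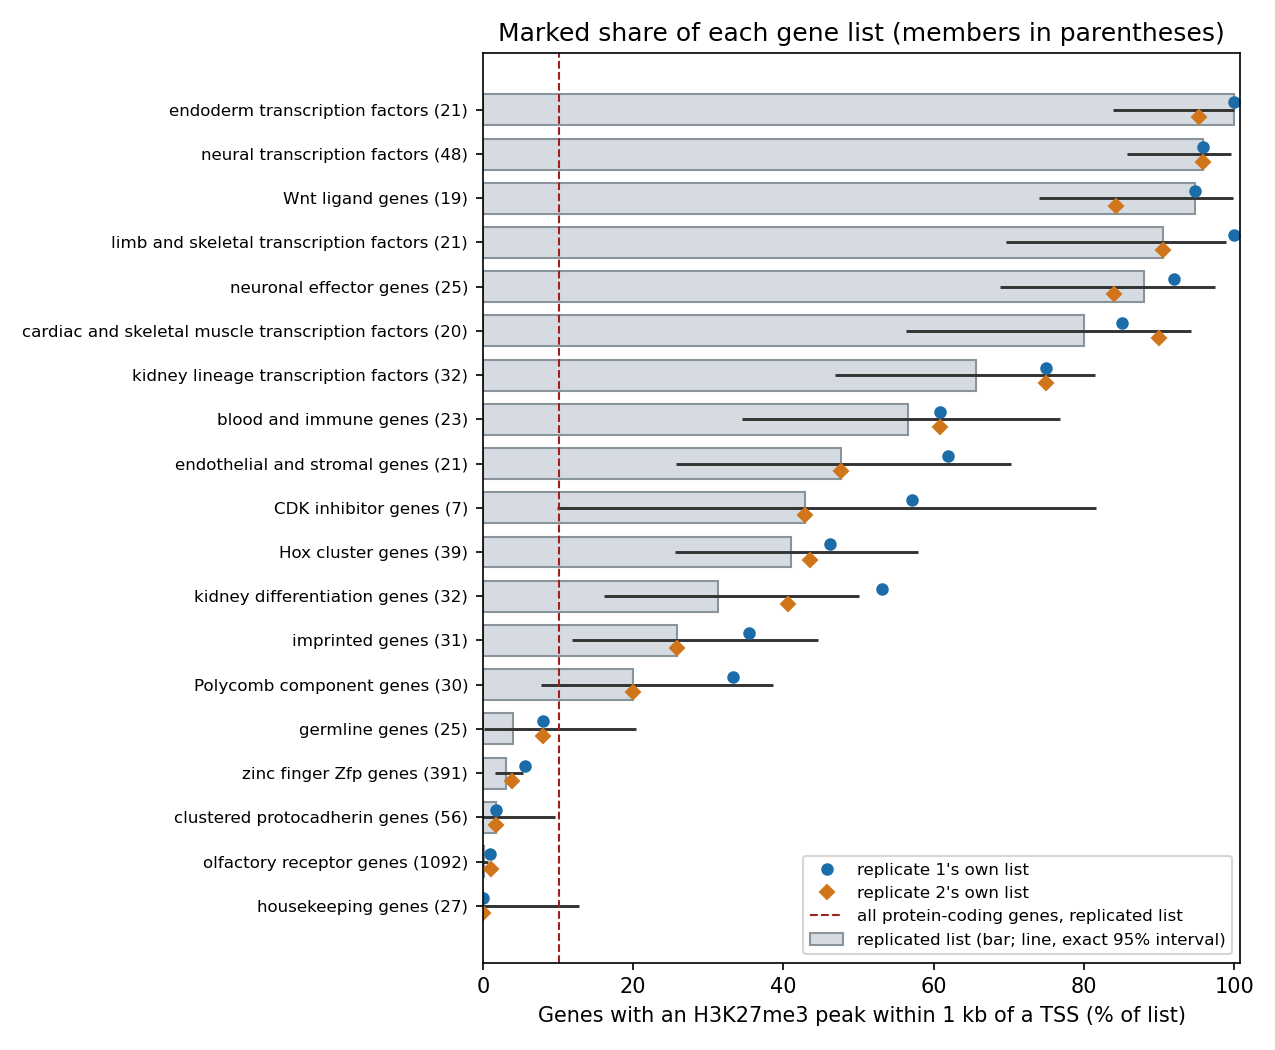
Marked share of each of 19 gene lists (horizontal axis, percent of the list's genes with a peak within 1 kb of a TSS). Bars and black lines give the replicated list's share and its exact 95% interval, circles and diamonds the shares from the lists of replicate 1 and replicate 2, and the dashed line the 10.1% of all protein-coding genes. Endoderm and neural factors stand at 100% and 95.8%, and olfactory receptor and housekeeping genes near 0.

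Kidney genes themselves were marked in part. Of 32 transcription factors that act in the nephron, collecting duct and stroma of the developing kidney, 21 were marked (65.6%, interval 46.8 to 81.4%, against 10.03% of other genes, exact adjusted p = 1.36e-13). Irx1 (fold 6.07), Foxd1 of the stromal progenitors (6.06), Six2 of the nephron progenitors (5.73), Irx2 (5.56), Six1 (5.37) and Lmx1b of the podocytes (5.37) led the list. The peaks of Irx2, Six1 and Lmx1b lay outside the 1 kb around the gene's 5′-most TSS and overlapped the window of another TSS. At Six2 the peak ran from 85689081 to 85690594 on chromosome 17. The strongest Six2 promoter peaks in the replicates' own lists had folds of 5.03 in replicate 1 and 5.92 in replicate 2. No replicated promoter peak was found at Pax2, Cited1, Hnf1a, Hnf4a, Hnf4g or Tcf21. Of these, Pax2 had a promoter peak in both replicates' own lists (3.14 and 3.02), and Hnf1a, Hnf4a and Hnf4g, regulators of proximal tubule and liver genes, had none in any list. Of 32 genes of differentiated kidney cells, 10 were marked (31.2% against 10.1%, exact adjusted p = 0.00128), and with replicate 1's list by itself 17 were (53.1% against 15.4%). The strongest were Nphs1 of the podocyte slit diaphragm (6.07), Slc27a2 (4.38), Cyp27b1 (4.12), Calb1 (4.05), Nphs2 (3.88) and Podxl (3.71). The Nphs1 peak ran from 30454957 to 30457343 on chromosome 7. Only its end reached the window of the 5′-most Nphs1 TSS at 30458315, so 6.07 may overstate the mark at this promoter. In the replicates' own lists the strongest Nphs1 promoter peaks had folds of 4.24 and 3.26. Nphs1 stayed marked with a 500 bp window, which the first peak does not reach. In list order, the first members without a replicated promoter peak were Slc34a1, Cubn, Aqp1, Slc5a2, Slc5a12 and Slc22a6.

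With the 1 kb window, the marked genes of the Hoxa and Hoxb clusters were those at the ends, and in the Hoxc cluster nearly all genes were marked. Of 39 Hox genes, 16 were marked (41.0%, exact adjusted p = 7.66e-07), and 11 with a 500 bp window, which lowered the difference from other genes from 31.0 to 19.3 points. In the Hoxa cluster Hoxa1 (fold 3.51) and Hoxa13 (4.32) were marked, and Hoxa2, Hoxa3, Hoxa4, Hoxa5, Hoxa6, Hoxa7, Hoxa9, Hoxa10 and Hoxa11 were not. In the Hoxb cluster Hoxb1 (2.70) and Hoxb13 (6.79) were marked, and Hoxb2 to Hoxb9 were not. The Hoxc cluster carried the mark at 8 of its 9 genes: Hoxc13 (6.07), Hoxc12 (5.03), Hoxc11 (4.89), Hoxc4 (4.14), Hoxc5 (3.60), Hoxc10 (3.0), Hoxc8 (2.86) and Hoxc6 (2.65), but not Hoxc9. In the Hoxd cluster Hoxd13 (5.39), Hoxd12 (4.89), Hoxd1 (4.38) and Hoxd3 (3.42) were marked, and Hoxd4, Hoxd8, Hoxd9, Hoxd10 and Hoxd11 were not, though Hoxd11 had a promoter peak in both replicates' own lists (3.71 and 2.47). Replicated peaks covered 31.6% of the span from the first to the last Hoxc TSS and 5.31% of the Hoxa span. Grouped after the values were seen, all 6 genes of paralogue groups 12 and 13 and all 3 of group 1 were marked, against 7 of 30 genes of groups 2 to 11. With a 500 bp window Hoxa1 and Hoxb1 of group 1, Hoxd12 of group 12, and Hoxc6 and Hoxc11 of groups 2 to 11 were not marked. Marking at the group 1 end of the Hoxa and Hoxb clusters thus depended on the window, and Hoxd1 was the only group 1 gene left. Some annotated Hox transcripts start far from the coding exons, so a marked TSS can lie beside another gene of the cluster.

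**Figure D2:**
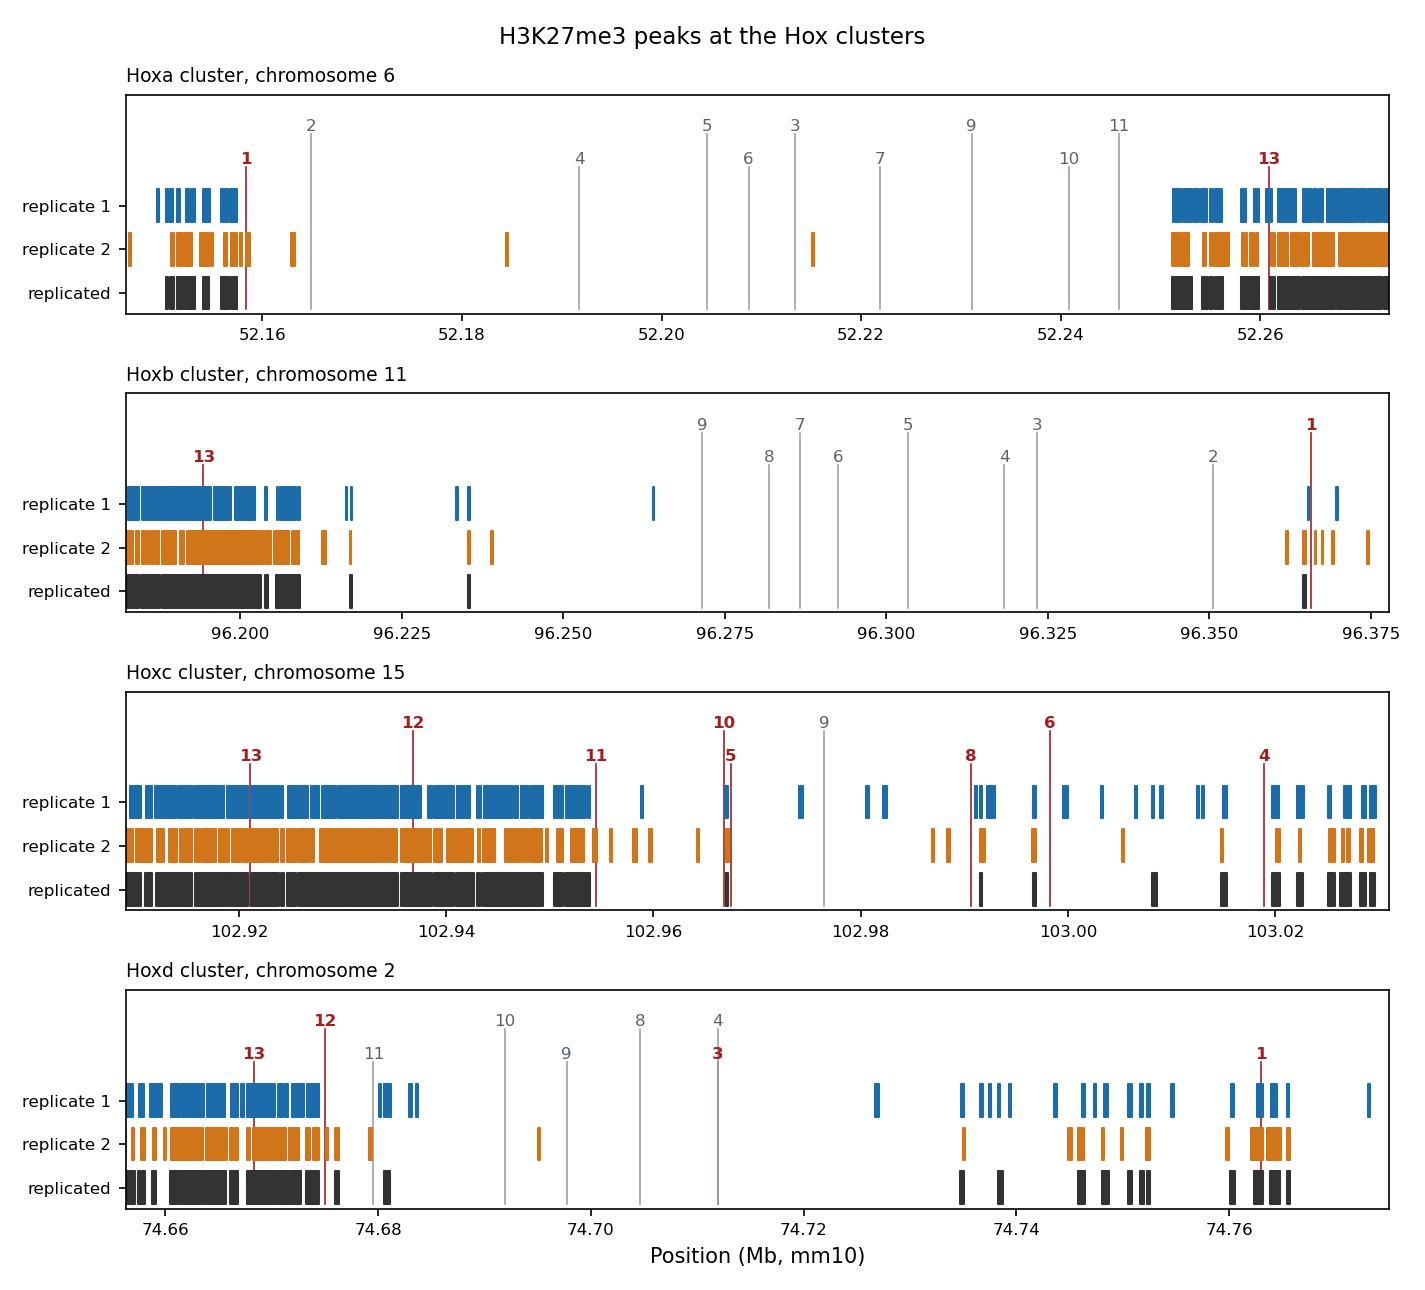
Peaks over the 4 Hox clusters (horizontal axis, position in Mb on mm10), with a row each for replicate 1, replicate 2 and the replicated list. Vertical lines stand at the 5′-most annotated TSS of each gene, numbered by paralogue group, in red and bold where any TSS of the gene was marked. Blocks of peaks fill the ends at groups 12 and 13, and peaks cover 31.6% of the Hoxc span.

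Genes of blood and of vessels and stroma, which a whole kidney also contains, were marked in part. Among 23 blood and immune genes 13 were marked (56.5%, exact adjusted p = 1.02e-07), led by Runx3 (fold 6.74), Pax5 (6.51), Gfi1 (5.69), Runx1 (4.86), Tal1 (4.55) and Irf4 (4.35). The erythroid genes Gata1 and Klf1 and the leukocyte genes Spi1, Tcf7, Bcl11b and Cebpe were not marked, though Bcl11b had a promoter peak in both replicates' own lists (2.46 and 4.15). Among 21 endothelial and stromal genes 10 were marked (47.6%, exact adjusted p = 2.15e-05), with Sox18 (5.53), Flt1 (5.23), Etv2 (5.10), Pdgfra (5.06), Erg (4.07) and Sox7 (3.98) the strongest. Pecam1, Cdh5, Tek, Tie1, Emcn and Plvap were not marked.

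Of 31 imprinted genes, 8 were marked (25.8% against 10.1%, exact adjusted p = 0.0138). These included Ascl2 (fold 6.24), Gnas (5.56), Igf2 (5.23), Dlk1 (4.72), Phlda2 (4.38) and Kcnq1 (4.28), and not Igf2r, Cdkn1c, Slc22a18, Tssc4, Ins2 or Ddc. The call was lost with replicate 2's list by itself (exact adjusted p = 0.0628, in a range from 0.00520 to 0.0628 over the alternatives). The cyclin-dependent kinase inhibitor genes Cdkn2a (5.86), Cdkn2b (4.47) and Cdkn2c (3.82) were marked and Cdkn1a, Cdkn1b, Cdkn1c and Cdkn2d were not, so that 3 of 7 passed Fisher's exact test (exact adjusted p = 0.0335). Against genes matched on promoter CpG this list did not pass (adjusted p = 0.121, permutation of gene sets), nor did it with a single TSS per gene (exact adjusted p = 0.138) or with replicate 2's list by itself (exact adjusted p = 0.0628), in a range from 0.00240 to 0.157 over the alternatives. Among 30 Polycomb component genes 6 were marked, Cbx8 (4.14), Pcgf5 (3.98), Bmi1 (3.88), Cbx2 (3.55), Cbx4 (3.37) and Cbx7 (2.94), a share of 20.0% against 10.1% of other genes that did not pass the test (exact adjusted p = 0.124). It passed with replicate 1's list by itself (exact adjusted p = 0.0193) and with the pooled list (exact adjusted p = 0.00731), in a range up to 0.616 over the alternatives. Ezh1, Ezh2, Eed, Suz12, Rbbp4 and Rbbp7, of which Ezh1 and Ezh2 encode the enzymes that place the mark, were not marked.

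Olfactory receptor, Zfp zinc finger and clustered protocadherin genes were marked less than other genes. Of 1092 olfactory receptor genes 2 were marked, Olfr94 (fold 3.63) and Olfr71 (2.87) (0.183% against 10.6%, exact adjusted p = 4.19e-47). Genes matched on promoter CpG were marked at 1.16%, so the difference shrank from -10.5 to -0.97 points (adjusted p = 9.5e-05, permutation of gene sets, the highest over the alternatives). Replicate 1's list by itself marked 11 olfactory receptor genes, replicate 2's 12 and the pooled list 13. Of 391 Zfp zinc finger genes 12 were marked (3.07% against 10.2%, exact adjusted p = 3.14e-07), with Zfp316 (5.90), Zfp385a (5.23), Zfp64 (4.89), Zfp536 (4.55), Zfp853 (3.88) and Zfp800 (3.82) the strongest, and 22 were marked with replicate 1's list by itself and 21 with the pooled list. Of 56 clustered protocadherin genes only Pcdhac2 was marked (4.06), which passed the test narrowly (exact adjusted p = 0.0493) and did not with a 500 bp window (exact adjusted p = 0.0706) or a single TSS per gene (exact adjusted p = 0.113), in a range from 0.00129 to 0.113 over the alternatives. The difference of clustered protocadherins from other genes was -8.35 points, and -13.7 with replicate 1's list by itself and -14.7 with the pooled list. None of 27 housekeeping genes, Actb, Gapdh, Ppia, Hprt, Tbp and Ubc among them, was marked (exact 95% interval 0 to 12.8%), which did not pass the test (exact adjusted p = 0.118). It did pass against genes matched on promoter CpG, of which 13.7% were marked (difference -13.7 points, adjusted p = 0.0443, permutation of gene sets), and with replicate 1's list by itself (-15.5 points, exact adjusted p = 0.0177), in a range from 0.0177 to 0.192 over the alternatives. Of 25 germline genes 1 was marked, Ddx25 (2.99), against 10.1% of other genes (exact adjusted p = 0.508). Dazl, Ddx4, Sycp1, Sycp2, Sycp3 and Mael had no promoter peak in any list.

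Peaks that stood close together formed broad domains. When replicated peaks were merged across gaps of up to 3 kb, 330 domains of at least 10 kb resulted. Their median length was 17.3 kb. Of the domains, 260 contained the 5′-most annotated TSS of a protein-coding gene. Domains that held only another TSS of a gene were not counted among these. The longest, on chromosome 9 from 91347499 to 91421271 (73.8 kb, 46 peaks), held Zic1 and Zic4, neighbouring genes of the hindbrain and cerebellum. It was followed by Dmbx1 (58.5 kb), Hoxc12 with Hoxc13 (56.4 kb), Pax3 (55.5 kb), Hand2 (49.9 kb), Tfap2a (46.8 kb), Gata4 (45.9 kb) and Hoxb13 (45.7 kb). A domain of 44.6 kb on chromosome 17 from 85449505 to 85494139 held no 5′-most TSS of a protein-coding gene, and the nearest belonged to Six3. The next held Cdkn2a and Cdkn2b (43.5 kb). In the Zic1 and Zic4 domain replicate 1's peaks covered 68.5% of the bases and replicate 2's 63.6%. The number of domains was 527 with replicate 1's list and 398 with replicate 2's.

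Replicated peaks lay at promoters more often than random positions did. Of the 12000 peaks, 3982 (33.2%) overlapped a promoter window, against a mean of 5.58% and a maximum of 6.27% in 1000 random placements on the same chromosomes (permutation p = 0.002, two-sided, the smallest these placements can give). A further 9.72% lay in exons of protein-coding genes, 19.3% in their introns and 37.8% outside them, where noncoding genes may lie. The means of 100 random placements were 6.47%, 31.1% and 56.9%. The share at promoters was 17.8% in replicate 1's list, 22.6% in replicate 2's and 19.6% in the pooled list.

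Peaks of one replicate were found again in the other more often than random placements were, though most were not found again. At least 50% of the length was covered by replicate 2 for 24.1% of replicate 1's peaks, against a mean of 0.427% in random placements, and by replicate 1 for 38.3% of replicate 2's peaks, against 0.558% (both permutation p = 0.001, one-sided, the smallest that 1000 placements can give). Sharing rose with peak strength. In 4 equal bins of fold, the share in replicate 1 was 10.4%, 12.7%, 20.7% and 52.7% from the weakest to the strongest, and in replicate 2 it was 19.6%, 25.4%, 37.4% and 71.0%. Over 9029 shared pairs, Spearman's rho of the folds was 0.402 and Pearson's r of the log2 folds 0.422, across peaks, which are not independent replicates. The replicated list held 29.0% of the pooled peaks (exact 95% interval 28.6 to 29.5%) and 58.2% of their bases, shares that also depend on whether its number was limited. Its peaks had a median fold of 3.54 and a median width of 594.5 bp, against 2.70 and 234 bp for the other pooled peaks.

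**Figure D3:**
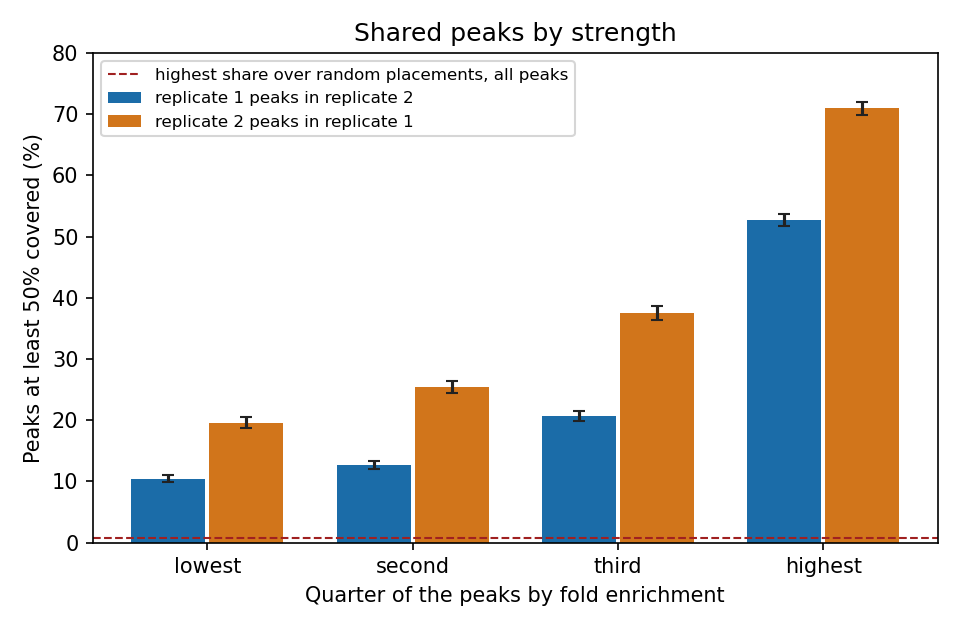
Share of peaks at least 50% covered by the other replicate (vertical axis, percent) in 4 equal bins of the authors' fold (horizontal axis), for replicate 1 and replicate 2. Error bars are exact 95% binomial intervals, and the dashed line is the highest share in random placements. The share rises from 10.4% to 52.7% in replicate 1 and from 19.6% to 71.0% in replicate 2.

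Some strong peaks of 1 replicate had no overlap with any peak of the other. In replicate 1 the highest by −log10 p was on chromosome 1 from 180934102 to 180934480, at the promoter of Lefty1 (fold 6.32), where replicate 2 had another peak in the promoter window (3.26). The next were at the promoter of Myrip (6.09), near Gata5 in its antisense transcript (5.83), in a Barhl2 intron (5.36) and in an Rnf220 exon (5.59). In replicate 2 the highest lay between genes on chromosome 3 from 96473813 to 96474414 (7.41). A pair of peaks in and near Cdkn2c (both 6.22), a peak near Nr3c2 (6.22) and an intergenic peak nearest to Six1 (5.79) followed. Some of these peaks lay inside broad domains that the other replicate's peaks also covered in part. Replicate 2's peaks covered 70.3% of the domain around the Barhl2 peak and 49.0% of that around the Rnf220 peak. Replicate 1's covered 49.4% of the domain around the peak in Cdkn2c and 56.0% of that around the peak nearest to Six1. The other named peaks lay in no such domain.

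Chromosome X carried different numbers of peaks in the replicates. Replicate 1 had 3399 peaks on X, 19.9 per Mb, which was 1.26 times the 15.8 per Mb of its autosomes. Replicate 2 had 856, 5.005 per Mb, which was 0.458 times the 10.9 per Mb of its autosomes. By covered bases X lay below the autosomes in both replicates: 5.13 against 5.79 kb per Mb in replicate 1, a ratio of 0.886, and 1.36 against 4.46 kb per Mb in replicate 2, a ratio of 0.306. On the autosomes, densities ran from 9.72 (chromosome 3) to 24.5 (chromosome 11) per Mb in replicate 1 and from 6.87 (chromosome 16) to 17.1 (chromosome 19) in replicate 2. Of replicate 1's X peaks 3.59% were shared with replicate 2, and their median width was 225 bp. The replicated list held 268 X peaks, 0.329 times its autosomal density.

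**Figure D4:**
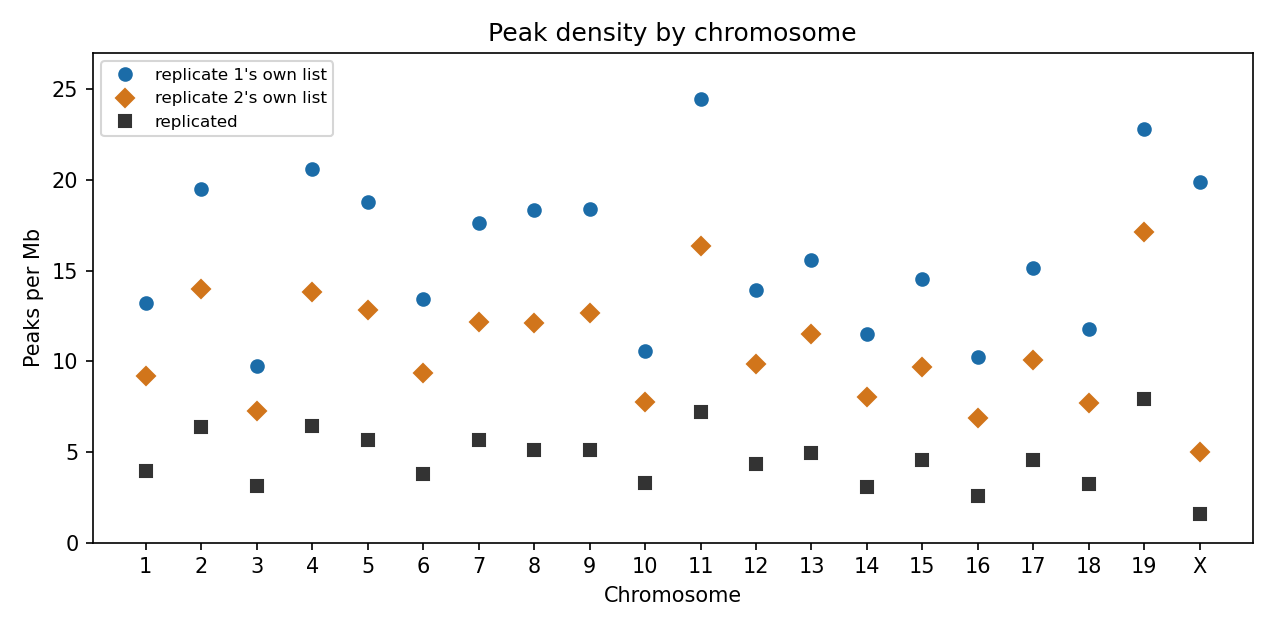
Peaks per Mb (vertical axis) on each chromosome (horizontal axis) in the lists of replicate 1 (circles) and replicate 2 (diamonds) and in the replicated list (squares). On X replicate 1 lies at 19.9 and replicate 2 at 5.005 peaks per Mb, a wider gap than on any autosome.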

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

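The tests with transcripts annotated protein_coding, with replicated peaks found in both replicates' own lists and without chromosome X were chosen after the data were seen. Over 10 alternatives each, the 19 list results gave 190 values, of which 178 kept their direction and their side of the threshold, 8 lost the call, 4 gained one and 0 reversed. All of the 12 changes were in 5 lists. Clustered protocadherins differed from other genes by -7.17 points with a 500 bp window, -6.82 with a single TSS per gene and -7.52 with replicated peaks found in both lists, where the call was lost. CDK inhibitors lost it at 20.0 points with a single TSS per gene, 19.3 with peaks found in both lists and 29.3 against the CpG-matched background. They also lost it without replicate 1 (29.7), and ranged from 29.7 to 41.7 with each replicate left out. Imprinted genes ranged from 12.6 to 20.1 points with each replicate left out and lost the call without replicate 1 (12.6). Polycomb components gained one with the pooled list (20.2 points) and without replicate 2, and ranged from 6.81 to 17.9 with each replicate left out. Housekeeping genes gained one against the CpG-matched background (-13.7 points) and without replicate 2, and ranged from -15.5 to -13.2 with each replicate left out. Marked genes numbered 3581 with the pooled list and 2867 to 3355 with each replicate left out, and of the 2198, 95.1% were kept without replicate 1 and 98.2% without replicate 2. Domains numbered 512 with 10 kb gaps, 644 with the pooled list and 398 to 527 with each replicate left out. The replicated share of pooled peaks was 17.7% when peaks 50% covered in both replicates were counted, 25.3% for peaks touched in both and 49.4% among peaks of q 0.01 or less. Spearman's rho of shared peaks was 0.366 at 1 bp, 0.486 with 50% of both peaks and 0.429 with −log10 p as strength. The X to autosome ratio was 0.458 to 1.26 with each replicate left out. For all of these the cause was not tested. The overlap of the replicates and the promoter share stayed above random placements under all alternatives run, with 14.1 to 41.5% of replicate 1's peaks shared and 17.8 to 49.1% of peaks at promoters. Of 110 named marked genes, 108 kept a promoter peak without replicate 1, 109 without replicate 2, 102 with a 500 bp window, 108 with peaks of q 0.01 or less and 99 with a single TSS per gene. No paired analysis was possible because there is 1 group. With the number of reads unknown, an unmarked gene is one without a peak at the authors' threshold, not one shown to lack the mark.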

Other observations

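Chosen only after the result was seen were the scan of gene families, the tests on X peaks of q 0.01 or less, on the peaks with the highest −log10 p and on the fold of kidney factors, the use of the CpG-matched background (an alternative fixed in advance) to weigh the marking of kidney factors, and the use of intervals to judge the shift of X and its relation to TSS density. In the scan, all protein-coding genes were sorted by the letters their symbols start with. Some families, the Nkx, Tbx, Sox, Cacna and Syt genes among them, share members with the lists fixed in advance and are not independent of them. Of 270 such families with at least 10 genes, 24 were marked more often than other genes and 7 less often (Fisher's exact test, two-sided, Benjamini-Hochberg over the 270). All 14 Nkx homeobox genes were marked (exact adjusted p = 6.11e-13). Channel and receptor genes were also among the higher families: 10 of 14 Cacna calcium channel genes (exact adjusted p = 3.38e-06), 9 of 14 Kcnk potassium channel genes (2.83e-05) and 8 of 14 Htr serotonin receptor genes (0.000358). So were 12 of 22 Fgf growth factor genes (8.20e-06), 11 of 19 Sox genes (1.05e-05), 9 of 13 Tbx genes (1.31e-05) and 10 of 17 Syt synaptotagmin genes (2.47e-05). Outside the clusters 9 of 12 protocadherin genes were marked (Fisher's exact adjusted p = 6.10e-06), Pcdh10 (fold 6.74) and Pcdh8 (6.57) the strongest. No gene was marked among 330 Vmn vomeronasal receptor genes (exact adjusted p = 4.38e-14), 67 Hist histone genes (0.0184), 64 Wdr genes (0.0240) and 54 Eif translation initiation factor genes (0.0477). The scan set each family against all other genes and was not matched on promoter CpG. For the olfactory receptor list such matching shrank the difference from -10.5 to -0.97 points. How far promoter CpG accounts for the family differences was not tested.

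Some of the strongest replicated peaks lay away from protein-coding promoters. A peak of 13694 bp on chromosome 7 from 79496229 to 79509922 (fold 8.09) covered Mir9-3 and its host transcript Mir9-3hg. A peak on chromosome 12 from 110187294 to 110189761 (7.92) overlapped the noncoding gene Gm34785, 89307 bp from the Dio3 TSS. A peak on chromosome 9 from 122568486 to 122570857 (8.26) overlapped no annotated gene. The nearest 5′-most TSS of a protein-coding gene, that of Topaz1, was 176489 bp away.

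Kidney lineage factors were marked at 21 of 32 genes in a tissue where such factors act. That is more than other genes, but less than factors of other lineages. In the neural, muscle, endoderm and limb lists together, 102 of 110 factors were marked (92.7%, Fisher's exact p = 0.000334, two-sided, unadjusted). This comparison of shares was also chosen after the result was seen. Against genes matched on promoter CpG a difference of 51.6 points remained (permutation of gene sets, adjusted p = 3.8e-05, the smallest the sets allow). This argues against CpG around the 5′-most TSS as the cause. CpG at a gene's other TSSs, where it can also be marked, was not matched. With peaks of q 0.01 or less, 21 kidney factors were still marked, a difference of 55.9 points (Fisher's exact adjusted p = 6.71e-14). That cut kept 93.7% of all replicated peaks, so it could remove little and does not decide whether weaker peaks carry the marking. A hypothesis is that the mark may be carried by part of the cells, those in which each factor is silent, which would lower its fold in whole tissue. The median promoter fold of the marked kidney factors (4.72) was lower than that of 102 marked factors of the neural, muscle, endoderm and limb lists (5.79, difference -1.07, permutation p = 0.00519, two-sided), but without the neural list the difference was -0.470 (permutation p = 0.160), so the hypothesis stays open. No expression or single-cell data were analysed here.

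The X chromosome had 1.26 times the autosomal peak density in replicate 1 and 0.458 times in replicate 2, but by covered bases 0.886 and 0.306 times, below the autosomes in both. Among replicate 1's 27748 strongest peaks by −log10 p, as many as replicate 2 has, the ratio was 0.803, and among peaks of q 0.01 or less it was 0.391 against 0.219 in replicate 2. A longer tail of weak peaks may thus hold part of the X peaks. At q 0.01 or less the odds ratio of X against autosomal peaks between the replicates was 1.79 (Fisher's exact p = 5.92e-09). That p counts single peaks, which are not independent, and covers no spread between libraries. The ratio in replicate 1 also kept falling with stricter cuts. Whether the tail is the whole cause therefore stays open. A shift of the whole X between the libraries, from the animals' sexes or from the control, cannot be told apart from no shift: at 119 shared X peaks the log2 ratio of replicate 1 to replicate 2 fold differed from that of autosomes by -0.0083 (95% bootstrap interval -0.080 to 0.118, permutation p = 0.728), and peaks found in both replicates are a small part of the X peaks. Marking of an inactive X in gene-rich parts is also open, since unshared replicate 1 peaks followed TSS density on X (Spearman's rho 0.490 over 1 Mb bins) as well as on the autosomes (median 0.513, range 0.206 to 0.742), and no biological explanation beyond these was tested.

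The peaks with the highest −log10 p were not those with the highest fold. A pair on chromosome 17, from 39843055 to 39846787 (fold 2.43, −log10 p 90.3) and from 39847868 to 39848904 (2.34, 82.8), overlapped an annotated ribosomal RNA gene, and 1 in an intron of Cdk8 on chromosome 5 from 146261003 to 146261480 had a fold of 5.17 and a −log10 p of 82.9. Under a Poisson model, their fold and −log10 p correspond to a background at least 45.1 times the median of replicated peaks for the ribosomal pair and 6.78 times for the Cdk8 peak. These factors restate the values the peaks were picked for and are no test of a repeat that the reference sequence holds in fewer copies than the genome, which stays open for all 3 peaks. No biological explanation of these peaks was tested.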
